A study of Homo sapiens with 13 samples.

How the data were processed

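RNA was sequenced from cardiomyocytes derived from the human induced pluripotent stem cell line 253G1, which carries a knocked-in Venus-Akaluc reporter. The 13 libraries fall into 5 groups by their labels: N-CM (non-expanded cardiomyocytes, n = 3), E-CM (expanded cardiomyocytes, n = 3), E-CM-B (expanded with BCH001, n = 3), E-CM-R (expanded with RG7834, n = 2) and N-CM-B (non-expanded with BCH001, n = 2). Libraries are named by group and replicate number, so that N-CM1 is replicate 1 of N-CM. Per the labels' protocols, RNA was extracted from frozen cells with a column kit, libraries were made with a Nextera kit and sequencing was on a NovaSeq instrument. The labels do not say that the replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

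The authors deposited a table of raw counts, in read pairs per gene, for 63140 genes. Per the file headers, read pairs were counted with featureCounts version 2.0.8 over exons, grouped by gene identifier, on the Ensembl GRCh38 annotation of release 112, without a strand setting and without multi-mapping reads. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.11b and featureCounts 2.0.6 on hg38, so the featureCounts version differs between the 2 sources. Because counting did not use strand, reads of a gene and of an overlapping or antisense partner cannot be told apart, which applies to HIF1A-AS3. Leaving out multi-mapping reads lowers the counts of near-identical genes, so values of HSPA1A, HLA-DQB1, HLA-C and the H1 histones are uncertain. The authors also deposited TPM values for 19638 genes with their symbols. The TPM values equal the counts divided by the summed exon length of the count table and scaled to the same total over those genes, with a largest relative difference of 4.996e-15. How those genes were chosen is not given in the sources used here. Identifiers were matched to a reference table of gene names, which gave a symbol for 62541 identifiers and none for 599. Coordinates are on GRCh38 as the count table gives them, from the first exon start to the last exon end.

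Depth ran from 13.0 to 35.3 M read pairs assigned to genes per library, and 21599 to 32621 genes had at least 1 read pair. The paths in the header of the count table put the 9 N-CM, E-CM and E-CM-B libraries in one folder and the 4 E-CM-R and N-CM-B libraries in another. The 4 libraries of the smaller folder had 13.0 to 19.9 M read pairs and the others 16.3 to 35.3 M. The folder was treated as a possible processing batch. For the comparisons that involve E-CM-R or N-CM-B, folder and group cannot be told apart. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 8.34 to 245 and correlations of log2 CPM across genes of 0.913 to 0.967, and no pair was treated as 1 library deposited in duplicate.

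Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the group factor, which left 19749 genes, 16558 of them with a symbol in the deposited TPM table. Library sizes were scaled by TMM, with factors from 0.896 to 1.21. The model had 1 term per group and no replicate block, all 13 libraries shared 1 dispersion estimate, and each comparison was tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An adjusted p in the text is from this test unless it is called a camera p. Fold changes are log2 values with standard errors (SE), and levels are TMM-scaled counts per M (CPM), as mean ± SD over the replicates. Against a group with no read pairs a fold is given as a lower bound, computed against a floor of 3 counts over that group, and against 1 to 3 counts the ratio is given with an exact 95% interval that covers counting error only. The tests, the alternatives and the genes and lists to name were set before the data were examined, except the comparison of E-CM-B with N-CM-B, the fits on the larger folder alone, the divisions and splits of libraries and the tests of explanations with their gene lists, which were added later.

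The 41 gene lists cover cardiomyocyte structure and identity, metabolism, stress responses, cell cycle, telomere and RNA-tailing factors, signalling targets and markers of other cell types. Each list was tested against the other genes with limma's camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the lists, again with a correlation estimated for each list, and with limma's fry. With an estimated correlation no list passed in any comparison (0 of 41, against 3 to 18 with the preset value), so its adjusted p stands beside each camera call. Counts of members are given over all genes tested and adjusted over the list alone. In parentheses after a library that was left out stands the adjusted p without it, of edgeR for a gene and of camera for a list.

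Genes were named by a rule. For expansion, for each compound in expanded cells and for BCH001 in non-expanded cells, it took the 10 largest rises and the 10 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 4 CPM over all libraries and no overlap between the libraries of the groups compared. For BCH001 against RG7834 it took 5 and 5 by the same conditions, and for the difference between the BCH001 effects 5 and 5 without the condition on overlap. Y-linked genes, XIST, symbols that are only clone or accession names, and pseudogenes were left out. It added a fixed set of telomerase, cell cycle, Wnt, sarcomere and heat shock genes whatever their result, up to 4 passing members of each list called by camera with the largest change, and up to 2 members of each list of another cell type. Where the text names fewer, it names those first in the ranking.

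Replicate numbers were taken to pair samples of 2 comparisons. Same-numbered deviations from group means correlated at 0.148 to 0.312 between N-CM and E-CM (unlike-numbered at most -0.00485). Between E-CM and E-CM-B these were 0.101 to 0.129 and at most 0.0905, over 3 pairs each. Values with replicate number as a block stand beside those counts. The alternatives were DESeq2 1.42.0 with its own size factors, RLE size factors, no low-count filter, a filter of at least 5 CPM in at least 2 libraries, a fit on the compared groups alone, the replicate block, limma on log2(TPM + 1) for 15449 genes with a mean TPM of at least 1, mitochondrially encoded genes left out, a test against a fold change of 1.5, and leaving out each library in turn. Under TPM the median of all genes moved by -0.36 (log2) for expansion, by -0.28, -0.34 and -0.50 for BCH001 in expanded cells, RG7834 in expanded cells and BCH001 in non-expanded cells, by -0.16 for expansion in BCH001-treated cells and by 0.21 for the difference between the BCH001 effects.

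The procedure was tested on simulated counts drawn from the means and library sizes of these data, with 200 genes changed in each comparison. At a 4-fold change it recovered 72 of 100 genes for expansion (19033 genes in the step), 74 for BCH001 in expanded cells (18917), 54 for RG7834 in expanded cells (18985), 51 for BCH001 in non-expanded cells (18989), 57 for BCH001 against RG7834 (19015), 18 for the difference between the BCH001 effects (18992) and 65 for expansion in BCH001-treated cells (18996). At a 2-fold change the numbers were 10, 8, 3, 0, 3, 2 and 1, and 0 to 2 unchanged genes were called. A simulated list shifted by 1.5-fold was called by camera in all 7 comparisons, and with an estimated correlation in each except the difference between the BCH001 effects.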

Results

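Poly-adenylation of short RNAs by PAPD5 (gene TENT4B) marks them for trimming, and the RNA component of telomerase (TERC) is among its known substrates. BCH001 and RG7834 are small-molecule inhibitors of this enzyme. The series applied them to human cardiomyocytes made from induced pluripotent stem cells and expanded in culture, and measured messenger and other RNA by sequencing. Differentiation started with 1 µM CHIR99021, an activator of Wnt signalling, and cells were purified in 4 mM lactate from day 9 to day 11. Expanded cells were replated on day 12, grown in 2 µM CHIR99021 and moved to 2 µM Wnt-C59, an inhibitor of Wnt secretion, on day 18. BCH001 was given at 10 µM and RG7834 at 1 µM from day 12 to day 20. The labels give no dose or timing for BCH001 in the non-expanded cells. A heat shock of 43 °C for 30 min on day 19 is stated for non-expanded and expanded cells with or without BCH001, and is not stated for RG7834. Cells were frozen on day 20.

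There were 3 N-CM, 3 E-CM, 3 E-CM-B, 2 E-CM-R and 2 N-CM-B libraries. Depth in M read pairs was 20.3, 20.7 and 35.3 for N-CM, 18.2, 16.3 and 25.2 for E-CM, 33.2, 28.3 and 32.0 for E-CM-B, 13.0 and 13.4 for E-CM-R, and 19.9 and 14.5 for N-CM-B, each in replicate order. The first principal component of log2 CPM carried 29.7% of the variance and the second 16.02%, on which E-CM2 lay apart from the other libraries at -139. TERC, the template RNA of telomerase, had 1 read pair in N-CM1 and 0 elsewhere, and TERT, its catalytic protein, 7 in N-CM2 and 0 elsewhere. Neither was testable with so few read pairs, and whether depth or library preparation set this limit was not tested. TENT4B itself did not pass edgeR's test in any comparison, with log2 changes of 0.11 on expansion (edgeR adjusted p = 0.907), 0.38 with BCH001 in expanded cells (edgeR adjusted p = 0.669), -0.24 with RG7834 (edgeR adjusted p = 0.834) and -0.08 with BCH001 in non-expanded cells (edgeR adjusted p = 0.961).

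The comparison of E-CM with N-CM asked how the expansion protocol changed the cardiomyocytes. FGF12, a fibroblast growth factor homolog that modulates sodium channels (chromosome 3, 192139390 to 192767764, minus strand), rose most among called genes with a mean of at least 4 CPM and no overlap between libraries, from 0.22 ± 0.382 to 65.3 ± 56.0 CPM (SD, n = 3 each; log2 change 8.42 ± 1.01 SE, edgeR adjusted p = 0.000907). The acute-phase gene SAA1 rose by 5.39 ± 0.75 (edgeR adjusted p = 0.00225), the zinc finger gene ZNF536 by 5.35 ± 0.71 (edgeR adjusted p = 0.0017), the actin nucleator COBL by 5.00 ± 1.28 (edgeR adjusted p = 0.045, or 0.0746 with the replicate block) and the water channel AQP4 by 4.85 ± 1.16. The largest falls by these limits were HIF1A-AS3 at -5.98 ± 0.78 (edgeR adjusted p = 0.00155), an antisense gene that overlaps HIF1A, and the catenin CTNNA2 at -5.96 ± 1.18. Of the Wnt genes set in advance, LEF1 fell by 1.34 ± 0.34 on the log2 scale (edgeR adjusted p = 0.0429) and AXIN2 was at -0.41 ± 0.51 (edgeR adjusted p = 0.717). COBL lost its call without N-CM1 (0.135), N-CM2 (0.0872), N-CM3 (0.123) or E-CM3 (0.287). AQP4 lost its call without N-CM1 (0.0886), N-CM2 (0.0832), N-CM3 (0.0992) or E-CM3 (0.0716). LEF1 lost its call without N-CM1 (0.109), N-CM2 (0.0719), N-CM3 (0.109), E-CM2 (0.0968) or E-CM3 (0.0791).

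Of 28 sarcomere genes on expansion, 9 rose, 1 fell and 18 did not pass (14 higher and 1 lower adjusted over the list alone). The sarcomere genes had a median log2 change of 0.79 (camera adjusted p = 2.46e-08, or 0.261 with an estimated correlation). TNNI3, the adult cardiac troponin I, rose by 2.52 ± 0.65, the atrial light chain MYL7 by 2.22 ± 0.29 and troponin C (TNNC1) by 2.13 ± 0.37, while the M-band gene MYOM2 was at -2.704 ± 0.68. The myosin heavy chains did not pass, at 2.44 ± 0.68 for MYH7 (edgeR adjusted p = 0.0613) and -0.16 ± 0.45 for MYH6 (edgeR adjusted p = 0.887). Of 10 cardiac stress markers, 3 rose and 7 did not pass (7 higher adjusted over the list alone). The cardiac stress markers had a median log2 change of 3.00 (camera adjusted p = 0.00185, or 0.402 with an estimated correlation). The rises were the titin-binding ANKRD1 at 4.29 ± 0.82, the natriuretic peptide NPPA at 3.55 ± 0.60 and the small heat shock protein CRYAB at 2.34 ± 0.27, and NPPB was at 4.59 ± 1.23 without passing (edgeR adjusted p = 0.0541). Of 27 p53 targets, 11 rose and 16 did not pass (16 higher adjusted over the list alone). The p53 targets had a median log2 change of 1.23 (camera adjusted p = 1.04e-09, or 0.382 with an estimated correlation). TP53I3 rose from 21.2 ± 3.32 to 152 ± 24.0 CPM (2.84 ± 0.23, edgeR adjusted p = 7.1e-05), and the cell cycle inhibitor CDKN1A (chromosome 6, 36676460 to 36687337, plus strand) from 238 ± 26.1 to 1585 ± 1014 CPM (2.73 ± 0.36, edgeR adjusted p = 0.0017). TNNI3 lost its call without N-CM1 (0.131), N-CM2 (0.065), N-CM3 (0.123), E-CM1 (0.142) or E-CM2 (0.0674). MYOM2 lost its call without N-CM1 (0.104), N-CM3 (0.109), E-CM1 (0.102) or E-CM2 (0.0968). ANKRD1 lost its call without N-CM2 (0.0531). MYH7 gained a call without E-CM3 (0.0105). NPPB gained a call without E-CM3 (0.00413).

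Of 17 glycolysis genes on expansion, 8 fell and 9 did not pass (12 lower adjusted over the list alone). The glycolysis genes had a median log2 change of -0.95 (camera adjusted p = 2.02e-06, or 0.402 with an estimated correlation). The neuronal enolase ENO2 was at -3.73 ± 0.71, the glucose transporter SLC2A1 at -3.54 ± 0.63 and hexokinase HK2 (chromosome 2, 74834127 to 74893359, plus strand) at -2.85 ± 0.31, from 394 ± 79.4 to 54.7 ± 12.7 CPM (edgeR adjusted p = 0.000604). Of 16 hypoxia response genes, 9 fell and 7 did not pass (13 lower adjusted over the list alone). The hypoxia genes had a median log2 change of -1.88 (camera adjusted p = 1.02e-09, or 0.382 with an estimated correlation). NDRG1 changed by -3.02 ± 0.66 and the glucose transporter SLC2A3 by -2.57 ± 0.29. Of 27 nuclear-encoded respiratory chain genes, 2 rose and 25 did not pass (19 higher adjusted over the list alone). The nuclear-encoded respiratory chain genes had a median log2 change of 0.74 (camera adjusted p = 5.36e-10, or 0.402 with an estimated correlation). Of 20 fatty acid oxidation genes, 4 rose and 16 did not pass (4 higher adjusted over the list alone). The fatty acid oxidation genes had a median log2 change of 0.55 (camera adjusted p = 0.0106, or 0.56 with an estimated correlation), and the median was -0.06 under TPM scaling. The cytosolic ribosomal proteins had a median log2 change of 0.47 (camera adjusted p = 8.19e-06, or 0.794 with an estimated correlation), and 0 of 46 passed edgeR (5 higher and 0 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone). NDRG1 lost its call without N-CM2 (0.0786), E-CM2 (0.0623) or E-CM3 (0.0507). Fatty acid oxidation genes lost their call without E-CM3 (0.144). Ribosomal proteins lost their call without N-CM3 (0.0600) or E-CM2 (0.193).

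Of 12 smooth muscle genes on expansion, 3 rose and 9 did not pass (9 higher adjusted over the list alone). The smooth muscle genes had a median log2 change of 1.21 (camera adjusted p = 5.44e-05, or 0.402 with an estimated correlation). The actin-binding TAGLN rose by 2.93 ± 0.74 and smooth muscle actin ACTA2 by 2.44 ± 0.29 (edgeR adjusted p = 0.000907). Of 13 endothelial genes, 1 fell and 12 did not pass (2 lower adjusted over the list alone). The endothelial genes had a median log2 change of -1.37 (camera adjusted p = 0.00381, or 0.402 with an estimated correlation), and KDR, a receptor for vascular endothelial growth factor, was at -2.42 ± 0.29. Of 11 endoderm and hepatic genes, 1 rose and 10 did not pass (7 higher adjusted over the list alone). The endoderm and hepatic genes had a median log2 change of 5.20 (camera adjusted p = 0.0226, or 0.599 with an estimated correlation). The rise was alpha-fetoprotein (AFP), which had 6665 read pairs in E-CM (6 in E-CM1, 1 in E-CM2 and 6658 in E-CM3) and 3 in N-CM. The ratio of 3214 (95% counting interval 1099 to 15589.8) thus rests on E-CM3 (edgeR adjusted p = 0.0377, or 0.052 with the replicate block), and without it the log2 change was 2.35. Of 15 atrial and nodal genes, 3 rose, 1 fell and 11 did not pass (5 higher and 1 lower adjusted over the list alone). The atrial and nodal genes had a median log2 change of 1.01 (camera adjusted p = 0.0226, or 0.382 with an estimated correlation). TAGLN lost its call without N-CM1 (0.105), N-CM2 (0.107), N-CM3 (0.13), E-CM1 (0.0783) or E-CM2 (0.103). AFP lost its call without N-CM1 (0.122), N-CM2 (0.108), N-CM3 (0.121) or E-CM3 (0.418). Endoderm and hepatic genes lost their call without N-CM1 (0.0557), N-CM3 (0.0923) or E-CM3 (0.849). Atrial and nodal genes lost their call without N-CM2 (0.118) or E-CM1 (0.0518).

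Of 19 calcium handling and ion channel genes, 2 rose and 17 did not pass (4 higher and 1 lower adjusted over the list alone). The calcium handling and channel genes had a median log2 change of 0.57 (camera adjusted p = 0.0263, or 0.599 with an estimated correlation). Of 17 senescence and secretory genes, 3 rose, 1 fell and 13 did not pass (5 higher and 2 lower adjusted over the list alone). The senescence genes had a median log2 change of 1.39 (camera adjusted p = 0.0317, or 0.684 with an estimated correlation), and the median was -0.05 under TPM scaling. Of 20 heat shock genes, 1 rose and 19 did not pass (6 higher adjusted over the list alone). The heat shock genes had a median log2 change of 0.37 (camera adjusted p = 0.00262, or 0.382 with an estimated correlation). HSPA1A, the inducible HSP70, was at 0.44 ± 0.25 (edgeR adjusted p = 0.345). Of 12 YAP targets, 2 rose and 10 did not pass (4 higher and 1 lower adjusted over the list alone). The YAP targets had a median log2 change of 0.56 (camera adjusted p = 0.0136, or 0.402 with an estimated correlation). The proliferation markers MKI67 and TOP2A were at -0.85 ± 0.53 and -1.38 ± 0.46 without passing (edgeR adjusted p = 0.408 and 0.113). The 11 telomerase complex genes had a median of 0.36 (camera adjusted p = 0.16), which was -0.02 under TPM scaling, and the 11 shelterin and CST genes, which bind telomere ends, one of -0.15 (camera adjusted p = 0.9746). Calcium handling and channel genes lost their call without N-CM2 (0.237) or E-CM3 (0.244). Senescence genes lost their call without N-CM3 (0.198) or E-CM1 (0.229).

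In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 822 of 19749 genes on expansion, 435 up and 387 down, and 3960 genes had an unadjusted p under 0.05, where chance gives 987. With the replicate number as a block the count was 1668, of which 814 were among the 822, and within the larger folder alone it was 214, or 673 with the block. Under TPM scaling 242 rose and 1546 fell (13.5% up, against 52.9%). A fit on N-CM and E-CM alone called 98 genes, 37 up and 61 down. The count was 353 without N-CM1 (166 up and 187 down), 467 without N-CM2 and 511 without N-CM3.

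**Figure D1:**
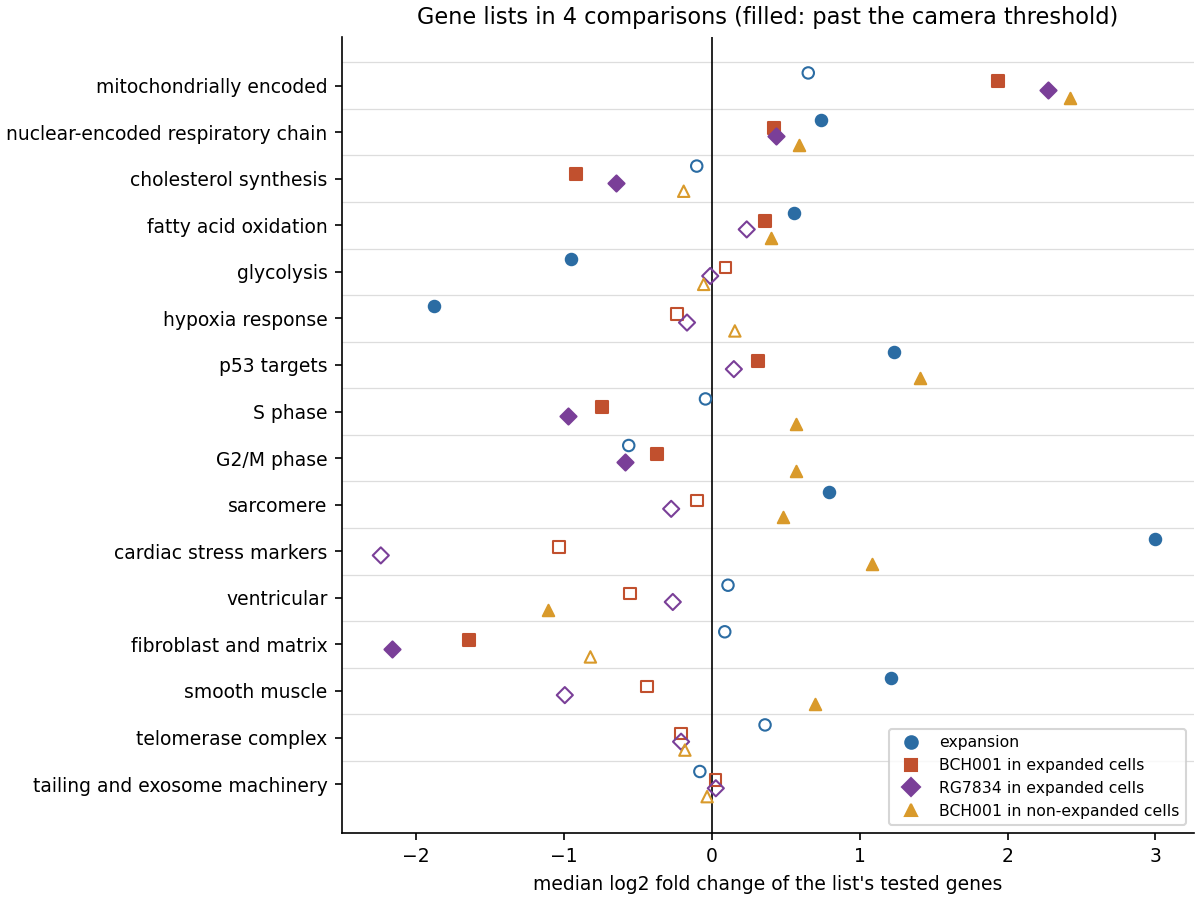
Median log2 fold change (x axis) of the tested members of 16 gene lists (y axis) in the 4 comparisons, with filled points where camera with the preset correlation passed and open points where it did not. Glycolysis (-0.95) and hypoxia response (-1.88) lay below 0 on expansion, and the mitochondrially encoded messages lay at 1.94, 2.27 and 2.42 in the compound comparisons.

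The comparison of E-CM-B with E-CM asked what BCH001 changed in expanded cells. HR, a nuclear corepressor, had 0 read pairs in E-CM and 418 in E-CM-B, at least 98.9-fold higher. The amino acid transporter gene SLC38A8 (chromosome 16, 84009667 to 84042795, minus strand) had 1108 against 3, a ratio of 254 (95% counting interval 86.8 to 1235) (edgeR adjusted p = 0.000935), and the peroxisomal transporter ABCD2 had a ratio of 219.6 (95% counting interval 60.5 to 1817) (edgeR adjusted p = 0.00412). KLF9, a transcription factor induced by nuclear hormone receptors (chromosome 9, 70384604 to 70414657, minus strand), rose from 0.59 ± 0.209 to 21.2 ± 5.06 CPM (SD, n = 3 each; log2 change 5.16 ± 0.54 SE, edgeR adjusted p = 0.00137). Also higher were PITPNM3 at 4.55 ± 0.82, VWC2 at 4.14 ± 0.53, the beta-1 adrenergic receptor ADRB1 at 3.75 ± 0.59 (edgeR adjusted p = 0.00963), POU5F1 at 3.70 ± 0.74, the apoptosis activator HRK at 3.67 ± 0.81 and EMID1 at 3.45 ± 0.31, which went from 2.00 ± 0.347 to 22.0 ± 2.48 CPM (edgeR adjusted p = 0.000707). The largest falls by those limits on CPM and overlap were the homeobox gene UNCX at -5.19 ± 0.98, PALD1 at -4.83 ± 0.88, the nerve growth factor receptor NGFR at -4.16 ± 0.63, the nodal antagonist LEFTY2 at -4.08 ± 0.54 (edgeR adjusted p = 0.00474) and CPXM1 at -3.58 ± 0.57. CDKN1A was at 0.53 ± 0.34 (edgeR adjusted p = 0.495), MYH7 at -2.96 ± 0.69 (edgeR adjusted p = 0.0534, or 0.0385 with the replicate block) and NPPB at -3.09 ± 1.15 (edgeR adjusted p = 0.211). HR lost its call without E-CM1 (0.0619), E-CM2 (0.0579), E-CM-B1 (0.0724), E-CM-B2 (0.0627) or E-CM-B3 (0.0553). POU5F1 lost its call without E-CM2 (0.0632), E-CM-B2 (0.0881) or E-CM-B3 (0.0595). HRK lost its call without E-CM1 (0.116), E-CM2 (0.118), E-CM-B1 (0.166) or E-CM-B3 (0.0661). UNCX lost its call without E-CM-B1 (0.0869), E-CM-B2 (0.0758) or E-CM-B3 (0.0797). PALD1 lost its call without E-CM-B1 (0.0534). CDKN1A gained a call without E-CM1 (0.0213). MYH7 gained a call without E-CM3 (0.00468). NPPB gained a call without E-CM3 (0.015).

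Of 13 mitochondrially encoded messages, 9 rose and 4 did not pass (12 higher adjusted over the list alone). The mitochondrial messages had a median log2 change of 1.94 (camera adjusted p = 8.53e-16, or 0.494 with an estimated correlation). The complex I subunit ND4 rose by 2.22 ± 0.37 (edgeR adjusted p = 0.0114), cytochrome b (CYTB) by 2.21 ± 0.43 and ND4L by 2.18 ± 0.36. The share of read pairs on the mitochondrial chromosome was 15.3% ± 1.10 (SD, n = 3) in E-CM-B against 4.18% ± 2.56 (SD, n = 3) in E-CM. The 27 nuclear-encoded respiratory chain genes had a median log2 change of 0.42 (camera adjusted p = 2.33e-05, or 0.617 with an estimated correlation), and 0 of 27 passed edgeR (8 higher and 0 lower at unadjusted p under 0.05, 1 and 0 by DESeq2, 1 higher adjusted over the list alone). Of 23 cholesterol synthesis genes, 8 fell and 15 did not pass (14 lower adjusted over the list alone). The cholesterol genes had a median log2 change of -0.92 (camera adjusted p = 3.36e-11, or 0.178 with an estimated correlation). Lanosterol synthase (LSS) was at -1.31 ± 0.24 and the sterol sensor INSIG1 at -1.30 ± 0.20 (edgeR adjusted p = 0.00912). CYTB lost its call without E-CM-B1 (0.0752), E-CM-B2 (0.0596) or E-CM-B3 (0.072). LSS lost its call without E-CM-B1 (0.0892) or E-CM-B2 (0.0722). INSIG1 lost its call without E-CM-B1 (0.0548).

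**Figure D2:**
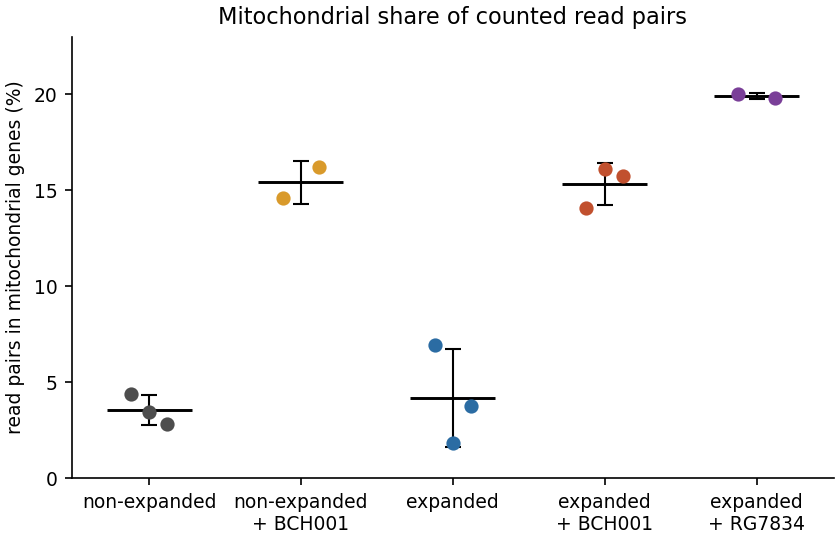
Percent of read pairs on the mitochondrial chromosome (y axis) in each of the 13 libraries by group (x axis), with points for libraries, a line at the group mean and a bar of 1 SD. The 7 compound-treated libraries lie between 14.1% and 20.0%, above the highest of the 6 untreated libraries at 6.93%.

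Of 36 S phase genes with BCH001 in expanded cells, 1 fell and 35 did not pass (10 lower adjusted over the list alone). The S phase genes had a median log2 change of -0.74 (camera adjusted p = 7.21e-06, or 0.602 with an estimated correlation), and the fall was UHRF1, which maintains DNA methylation, at -2.48 ± 0.51. Of 34 G2/M genes, 0 passed edgeR (0 higher and 2 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone). The G2/M genes had a median log2 change of -0.37 (camera adjusted p = 0.0299, or 0.878 with an estimated correlation) and a camera adjusted p of 0.0585 with the replicate block. Of 22 fibroblast and matrix genes, 3 fell and 19 did not pass (13 lower adjusted over the list alone). The fibroblast and matrix genes had a median log2 change of -1.64 (camera adjusted p = 5.85e-06, or 0.602 with an estimated correlation), where MFAP4 was at -2.28 ± 0.38. Of 17 immediate early genes, 2 fell and 15 did not pass (5 lower adjusted over the list alone). The immediate early genes had a median log2 change of -1.26 (camera adjusted p = 0.00877, or 0.494 with an estimated correlation), where IER2 was at -1.90 ± 0.35. Of 13 NF-kB targets, 0 passed edgeR (0 higher and 8 lower at unadjusted p under 0.05, 0 and 2 by DESeq2, 2 lower adjusted over the list alone). The NF-kB targets had a median log2 change of -0.89 (camera adjusted p = 0.00187, or 0.494 with an estimated correlation). Of 11 endoderm and hepatic genes, 0 passed edgeR (0 higher and 6 lower at unadjusted p under 0.05, 0 and 1 by DESeq2, 6 lower adjusted over the list alone). The endoderm and hepatic genes had a median log2 change of -2.84 (camera adjusted p = 0.0473, or 0.712 with an estimated correlation) and a camera adjusted p of 0.0582 with the replicate block. UHRF1 lost its call without E-CM2 (0.0611), E-CM-B1 (0.123) or E-CM-B2 (0.0982). MFAP4 lost its call without E-CM-B2 (0.0555) or E-CM-B3 (0.0595). IER2 lost its call without E-CM-B2 (0.0693) or E-CM-B3 (0.0649). G2/M genes lost their call without E-CM2 (0.55), E-CM-B1 (0.418) or E-CM-B3 (0.21). Immediate early genes lost their call without E-CM-B3 (0.0595). Endoderm and hepatic genes lost their call without E-CM3 (0.777, with the direction turned to higher), E-CM-B2 (0.155) or E-CM-B3 (0.0782).

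The 46 ribosomal protein genes had a median of -0.52 (camera adjusted p = 0.000246, or 0.878 with an estimated correlation), and 0 of 46 passed edgeR (0 higher and 6 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone). The 12 YAP targets were at -0.73 (camera adjusted p = 0.0118, or 0.57 with an estimated correlation), and 0 of 12 passed edgeR (0 higher and 5 lower at unadjusted p under 0.05, 0 and 1 by DESeq2, 0 adjusted over the list alone). The 20 fatty acid oxidation genes were at 0.36, or -0.04 under TPM scaling (camera adjusted p = 0.0118, or 0.617 with an estimated correlation), and 0 of 20 passed edgeR (5 higher and 0 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone). The 27 p53 targets were at 0.31, or -0.02 under TPM scaling (camera adjusted p = 0.00543, or 0.617 with an estimated correlation), and 0 of 27 passed edgeR (2 higher and 0 lower at unadjusted p under 0.05, 1 and 0 by DESeq2, 1 higher adjusted over the list alone). The telomerase complex was at -0.21 (camera adjusted p = 0.603), and the 28 genes of the RNA tailing and exosome machinery at 0.02, or -0.28 under TPM scaling (camera adjusted p = 0.847). HSPA1A fell by 1.13 ± 0.25 on the log2 scale (edgeR adjusted p = 0.0457). HSPA1A lost its call without E-CM2 (0.0978), E-CM-B1 (0.115), E-CM-B2 (0.118) or E-CM-B3 (0.14). Ribosomal proteins lost their call without E-CM2 (0.717) or E-CM-B3 (0.0564). YAP targets lost their call without E-CM2 (0.0756) or E-CM-B2 (0.144). Fatty acid oxidation genes lost their call without E-CM1 (0.0856) or E-CM-B2 (0.283). p53 targets lost their call without E-CM2 (0.17) or E-CM3 (0.114).

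In all, edgeR called 280 genes with BCH001 in expanded cells, 109 up and 171 down, and 3117 had an unadjusted p under 0.05. A fit on E-CM and E-CM-B alone called 5 genes. With the replicate block the count was 536, of which 270 were among the 280, and within the larger folder alone it was 51, or 105 with the block. Under TPM scaling 116 rose and 946 fell (10.9% up, against 38.9%), and without a low-count filter 376 rose and 900 fell. The count was 164 without E-CM1 (87 up and 77 down), 81 without E-CM-B1 (48 and 33), 127 without E-CM-B2 (64 and 63) and 101 without E-CM-B3 (51 and 50), where falls were no longer the larger part, and 184 without E-CM2 (81 and 103) and 980 without E-CM3 (321 and 659).

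The comparison of E-CM-R with E-CM asked what the other inhibitor changed. The same leading genes rose: HR was at least 178-fold higher (0 read pairs in E-CM, 215 in E-CM-R), ABCD2 had a ratio of 278 (95% counting interval 76.2 to 2313) (edgeR adjusted p = 0.00346), SLC38A8 a ratio of 207 (95% counting interval 70.1 to 1012) (edgeR adjusted p = 0.00181) and KLF9 went from 0.59 ± 0.209 (SD, n = 3) to 26.6 ± 0.119 CPM (SD, n = 2; log2 change 5.49 ± 0.57 SE, edgeR adjusted p = 0.00181). VWC2 was at 3.89 ± 0.55, ADRB1 at 3.69 ± 0.62, SPTLC3, a subunit of serine palmitoyltransferase, at 3.18 ± 0.42, ECEL1 at 3.11 ± 0.57, the interferon regulator IRF1 at 3.10 ± 0.40 and EMID1 (chromosome 22, 29205896 to 29259597, plus strand) at 3.10 ± 0.32 (edgeR adjusted p = 0.00181). Among the falls, UNCX had no read pairs in E-CM-R and was at least 69.6-fold lower, the collectin COLEC11 was at -5.66 ± 1.15, the degradation factor DERL3 at -5.51 ± 0.88 and NGFR at -5.04 ± 0.81. MYH7 was at -3.74 ± 0.85 (edgeR adjusted p = 0.0589) and NPPB at -5.91 ± 1.58 (edgeR adjusted p = 0.102) without passing. HR lost its call without E-CM1 (0.0551), E-CM2 (0.0547), E-CM-R1 (0.127) or E-CM-R2 (0.192). VWC2 lost its call without E-CM-R1 (0.0767) or E-CM-R2 (0.0733). ADRB1 lost its call without E-CM-R1 (0.198) or E-CM-R2 (0.117). SPTLC3 lost its call without E-CM-R1 (0.0737) or E-CM-R2 (0.0733). ECEL1 lost its call without E-CM1 (0.0678), E-CM2 (0.0674), E-CM-R1 (0.24) or E-CM-R2 (0.1998). IRF1 lost its call without E-CM-R2 (0.107). UNCX lost its call without E-CM-R1 (0.363) or E-CM-R2 (0.339). COLEC11 lost its call without E-CM1 (0.0747), E-CM2 (0.0705), E-CM-R1 (0.349) or E-CM-R2 (0.441). DERL3 lost its call without E-CM-R1 (0.235) or E-CM-R2 (0.174). NGFR lost its call without E-CM-R1 (0.212) or E-CM-R2 (0.228). MYH7 gained a call without E-CM3 (0.00407). NPPB gained a call without E-CM3 (0.00400).

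Of 13 mitochondrially encoded messages, 10 rose and 3 did not pass (13 higher adjusted over the list alone). The mitochondrial messages had a median log2 change of 2.27 (camera adjusted p = 4.25e-16, or 0.477 with an estimated correlation), led by ND5 at 2.85 ± 0.49 and CYTB at 2.78 ± 0.47, and the mitochondrial share was 19.9% ± 0.162 (SD, n = 2). The respiratory chain genes of the nucleus had a median of 0.43 (camera adjusted p = 0.000788, or 0.62 with an estimated correlation), and 0 of 27 passed edgeR (6 higher and 0 lower at unadjusted p under 0.05, 1 and 0 by DESeq2, 0 adjusted over the list alone). Of 23 cholesterol synthesis genes, 2 fell and 21 did not pass (9 lower adjusted over the list alone). The cholesterol genes had a median log2 change of -0.65 (camera adjusted p = 3.34e-06, or 0.477 with an estimated correlation), where INSIG1 was at -1.32 ± 0.23. Of 36 S phase genes, 0 passed edgeR (0 higher and 17 lower at unadjusted p under 0.05, 0 and 10 by DESeq2, 12 lower adjusted over the list alone). The S phase genes had a median log2 change of -0.98 (camera adjusted p = 8.39e-08, or 0.62 with an estimated correlation). Of 34 G2/M genes, 0 passed edgeR (0 higher and 4 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone). The G2/M genes had a median log2 change of -0.59 (camera adjusted p = 0.0178, or 0.745 with an estimated correlation). Of 22 fibroblast and matrix genes, 1 fell and 21 did not pass (11 lower adjusted over the list alone). The fibroblast and matrix genes had a median log2 change of -2.17 (camera adjusted p = 6.73e-06, or 0.62 with an estimated correlation), and MFAP4 was at -2.67 ± 0.46. The 14 small nucleolar and Cajal body RNAs had a median of 1.85 (camera adjusted p = 0.0272, or 0.62 with an estimated correlation), and 0 of 14 passed edgeR (1 higher and 1 lower at unadjusted p under 0.05, 0 and 1 by DESeq2, 0 adjusted over the list alone). The ribosomal proteins were at -0.60 (camera adjusted p = 0.00025, or 0.745 with an estimated correlation), and 0 of 46 passed edgeR (0 higher and 2 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone), and the NF-kB targets at -1.17 (camera adjusted p = 0.0178, or 0.62 with an estimated correlation), and 0 of 13 passed edgeR (0 higher and 4 lower at unadjusted p under 0.05, 0 and 1 by DESeq2, 0 adjusted over the list alone). ND5 lost its call without E-CM-R1 (0.167) or E-CM-R2 (0.153). CYTB lost its call without E-CM-R1 (0.165) or E-CM-R2 (0.129). INSIG1 lost its call without E-CM1 (0.0618), E-CM-R1 (0.41) or E-CM-R2 (0.228). MFAP4 lost its call without E-CM-R1 (0.278) or E-CM-R2 (0.281). G2/M genes lost their call without E-CM2 (0.241). Small nucleolar and Cajal body RNAs lost their call without E-CM2 (0.107) or E-CM-R2 (0.339). Ribosomal proteins lost their call without E-CM2 (0.439). NF-kB targets lost their call without E-CM1 (0.167) or E-CM-R2 (0.0704).

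In all, edgeR called 194 genes with RG7834, 82 up and the others down, and 2810 had an unadjusted p under 0.05. A fit on E-CM and E-CM-R alone called 0 genes. Under TPM scaling 106 rose and 1322 fell (7.42% up, against 42.3%). The count was 983 without E-CM3 (359 up, 624 down), 136 without E-CM1 (76 and 60), 5 without E-CM-R1 and 8 without E-CM-R2, with no fall in the last pair. E-CM-R came from the other folder and its heat shock is not stated, so batch and compound cannot be told apart here.

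BCH001 and RG7834 were given at different doses, 10 and 1 µM, over the same days. Of the 280 and 194 genes edgeR called with BCH001 and with RG7834 in expanded cells, 67 rose with both (0.453 expected of independent lists) and 57 fell with both (0.970 expected), and 0 went opposite ways. The log2 fold changes correlated at 0.65 across genes, which are not independent replicates, against a mean of 0.42 (0.386 to 0.441) in 20 simulations of unchanged groups against the shared E-CM libraries, and the covariance was 1.41 against 0.345. The simulations may miss shifts of whole libraries, as in E-CM2. With the 3 E-CM libraries divided between the comparisons, in 6 ways chosen after the results were seen, 9 to 97 genes went the same way (at most 6.27 expected), the correlation was 0.0884 to 0.281 and the covariance 0.277 to 0.902, so part of both undivided values may come from the shared controls. In the direct comparison the log2 difference, BCH001 minus RG7834, was -0.32 (95% interval -1.37 to 0.72) for KLF9, 0.32 (95% interval -0.75 to 1.401) for SLC38A8, 0.24 (95% interval -0.88 to 1.36) for VWC2, 0.35 (95% interval -0.32 to 1.02) for EMID1, -0.27 (95% interval -1.10 to 0.57) for ND4 and 0.01 (95% interval -0.47 to 0.50) for INSIG1 (edgeR adjusted p = 1 for each).

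Between the compounds edgeR called 0 genes (801 at unadjusted p under 0.05, against 987 by chance) and DESeq2 9. The median 95% interval reached 1.12 (log2) to either side. NPPA was at 1.54 ± 0.64 and TNNI3 at 2.35 ± 0.76 (edgeR adjusted p = 1 for both). Folder, dose and stated heat shock also differ, so they cannot be told from compound in the 3 lists camera called. The cardiac stress markers were higher with BCH001 than with RG7834 (median log2 change 1.10, camera adjusted p = 0.0256, or 0.866 with an estimated correlation) and 0 of 10 passed edgeR (2 higher and 0 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone). The immediate early genes were lower (median log2 change -0.64, camera adjusted p = 0.00077, or 0.629 with an estimated correlation), and 0 of 17 passed edgeR (0 higher and 3 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 2 lower adjusted over the list alone). The endoderm and hepatic genes were lower (median log2 change -4.10, camera adjusted p = 4.42e-05, or 0.866 with an estimated correlation, and a median of -4.17 with genes at 0 read pairs set at their bound), and 0 of 11 passed edgeR (0 higher and 6 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 1 lower adjusted over the list alone). Cardiac stress markers lost their call without E-CM-B1 (0.271) or either E-CM-R library, and immediate early genes without E-CM-B3 (0.0889) or E-CM-R2.

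The comparison of N-CM-B with N-CM asked what BCH001 changed without expansion. SLC38A8 had no read pairs in N-CM and was at least 368-fold higher. CEL, the bile salt-dependent lipase (chromosome 9, 133061981 to 133071861, plus strand), rose from 0.47 ± 0.242 (SD, n = 3) to 55.8 ± 0.159 CPM (SD, n = 2; log2 change 6.83 ± 0.45 SE, edgeR adjusted p = 1.83e-05), and KLF9 from 0.173 ± 0.151 to 17.8 ± 0.569 CPM (6.54 ± 0.61, edgeR adjusted p = 0.000266). HR rose by 6.60 ± 1.21, the actin-binding signalling gene ABRA by 6.38 ± 0.83 (edgeR adjusted p = 0.00287), XIRP2 by 6.18 ± 0.97, MARCHF11 by 6.02 ± 0.84 (edgeR adjusted p = 0.00379) and ADRB1 by 5.56 ± 0.63 (edgeR adjusted p = 0.00116). The homeobox gene HOXB1 was lower by a ratio of 161 (95% counting interval 54.9 to 782), the retinoic acid synthesis enzyme ALDH1A2 was at -7.28 ± 1.74, the growth factor FGF16 was lower by a ratio of 161 (95% counting interval 55.0 to 782) and UNCX was at -6.30 ± 1.25. HR lost its call without N-CM1 (0.0583), N-CM-B1 (0.0849) or N-CM-B2 (0.112). XIRP2 lost its call without N-CM-B2 (0.0528). HOXB1 lost its call without N-CM-B1 (0.276) or N-CM-B2 (0.188). ALDH1A2 lost its call without N-CM1 (0.158), N-CM2 (0.0706), N-CM-B1 (0.468) or N-CM-B2 (0.299). FGF16 lost its call without N-CM-B1 (0.0849) or N-CM-B2 (0.0565). UNCX lost its call without N-CM2 (0.0558), N-CM-B1 (0.237) or N-CM-B2 (0.269).

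Of 27 p53 targets, 8 rose and 19 did not pass (17 higher adjusted over the list alone). The p53 targets had a median log2 change of 1.404 (camera adjusted p = 2.72e-12, or 0.515 with an estimated correlation). CDKN1A rose from 238 ± 26.1 to 1682 ± 60.8 CPM (2.82 ± 0.38, edgeR adjusted p = 0.00346), the death receptor FAS by 2.55 ± 0.52 and TP53I3 by 2.53 ± 0.24 (edgeR adjusted p = 0.000266). Of 13 mitochondrially encoded messages, 11 rose and 2 did not pass (13 higher adjusted over the list alone). The mitochondrial messages had a median log2 change of 2.42 (camera adjusted p = 9.47e-15, or 0.515 with an estimated correlation), led by CYTB at 3.01 ± 0.47, and the mitochondrial share was 15.4% ± 1.13 (SD, n = 2) against 3.54% ± 0.782 (SD, n = 3) in N-CM. Of 10 cardiac stress markers, 2 rose and 8 did not pass (4 higher adjusted over the list alone). The cardiac stress markers had a median log2 change of 1.08 (camera adjusted p = 0.00447, or 0.533 with an estimated correlation), where CRYAB was at 3.16 ± 0.30 (edgeR adjusted p = 0.000266). Of 28 sarcomere genes, 3 rose and 25 did not pass (6 higher and 1 lower adjusted over the list alone). The sarcomere genes had a median log2 change of 0.48 (camera adjusted p = 0.0154, or 0.533 with an estimated correlation), where MYL7 was at 1.39 ± 0.31. Of 10 ventricular genes, 3 fell and 7 did not pass (1 higher and 5 lower adjusted over the list alone). The ventricular genes had a median log2 change of -1.11 (camera adjusted p = 0.0117, or 0.515 with an estimated correlation), and the falls were IRX4 at -3.66 ± 0.80, PRDM16 at -2.38 ± 0.34 and LBH at -2.10 ± 0.21 (edgeR adjusted p = 0.000357). FAS lost its call without N-CM1 (0.102), N-CM3 (0.0674), N-CM-B1 (0.139) or N-CM-B2 (0.177). CYTB lost its call without N-CM-B2 (0.0545). MYL7 lost its call without N-CM1 (0.0785), N-CM2 (0.0944), N-CM3 (0.08868), N-CM-B1 (0.129) or N-CM-B2 (0.332). IRX4 lost its call without N-CM1 (0.103), N-CM2 (0.0706), N-CM-B1 (0.32) or N-CM-B2 (0.307). PRDM16 lost its call without N-CM-B1 (0.0929) or N-CM-B2 (0.0528). Sarcomere genes lost their call without N-CM2 (0.0767) or N-CM-B2 (0.0631).

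Of 20 Wnt target genes, 3 fell and 17 did not pass (3 lower adjusted over the list alone). The Wnt target genes had a median log2 change of -0.47 (camera adjusted p = 0.0198, or 0.533 with an estimated correlation) (median -0.42 without the gene that had too few read pairs), with MSX2 at -2.84 ± 0.52 and TBX3 at -2.48 ± 0.46. Of 19 calcium handling and ion channel genes, 2 rose and 17 did not pass (5 higher and 1 lower adjusted over the list alone). The calcium handling and channel genes had a median log2 change of 0.49 (camera adjusted p = 0.0117, or 0.55 with an estimated correlation), or a median of -0.04 under TPM scaling, and the rises were the potassium channel KCND3 at 2.698 ± 0.63 and phospholamban (PLN) at 2.29 ± 0.41. Of 13 endothelial genes, 1 rose, 1 fell and 11 did not pass (1 higher and 1 lower adjusted over the list alone). The endothelial genes had a median log2 change of -1.75 (camera adjusted p = 0.0300, or 0.575 with an estimated correlation), where KDR was at -2.33 ± 0.34. Of 36 S phase genes, 1 fell and 35 did not pass (1 higher and 1 lower adjusted over the list alone). The S phase genes had a median log2 change of 0.57 (camera adjusted p = 0.0117, or 0.575 with an estimated correlation). Of 34 G2/M genes, 0 passed edgeR (3 higher and 0 lower at unadjusted p under 0.05, 2 and 0 by DESeq2, 0 adjusted over the list alone). The G2/M genes had a median log2 change of 0.57 (camera adjusted p = 9.47e-05, or 0.575 with an estimated correlation). MKI67 and TOP2A were at 0.58 ± 0.58 and 0.28 ± 0.51 (edgeR adjusted p = 0.714 and 0.864). Of 11 epicardial genes, 1 fell and 10 did not pass (2 lower adjusted over the list alone). The epicardial genes had a median log2 change of -4.09 (camera adjusted p = 0.0429, or 0.575 with an estimated correlation) (median -3.70 with genes at 0 read pairs at their bound), and the fall was ALDH1A2. MSX2 lost its call without N-CM-B1 (0.22) or N-CM-B2 (0.129). TBX3 lost its call without N-CM-B1 (0.193) or N-CM-B2 (0.177). KCND3 lost its call without N-CM1 (0.106), N-CM2 (0.117), N-CM-B1 (0.453) or N-CM-B2 (0.129). PLN lost its call without N-CM1 (0.0545), N-CM2 (0.0523) or N-CM-B1 (0.177). KDR lost its call without N-CM-B1 (0.0839) or N-CM-B2 (0.0634). Wnt target genes lost their call without N-CM1 (0.0823) or N-CM-B1 (0.0792). Calcium handling and channel genes lost their call without N-CM2 (0.0825). Endothelial genes lost their call without N-CM2 (0.246) or N-CM-B2 (0.0631). S phase genes lost their call without N-CM2 (0.273). G2/M genes lost their call without N-CM2 (0.0815). Epicardial genes lost their call without N-CM1 (0.261), N-CM2 (0.0767), N-CM-B1 (0.0792) or N-CM-B2 (0.0631).

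The nuclear-encoded respiratory chain had a median of 0.59 (camera adjusted p = 5.52e-07, or 0.533 with an estimated correlation), and 0 of 27 passed edgeR (15 higher and 1 lower at unadjusted p under 0.05, 3 and 0 by DESeq2, 0 adjusted over the list alone). Fatty acid oxidation was at 0.40, or -0.14 under TPM scaling (camera adjusted p = 0.0141, or 0.575 with an estimated correlation), and 0 of 20 passed edgeR (3 higher and 0 lower at unadjusted p under 0.05, 2 and 0 by DESeq2, 0 adjusted over the list alone). The replication-dependent histones were at 0.87 (camera adjusted p = 0.00334, or 0.533 with an estimated correlation), and 0 of 24 passed edgeR (6 higher and 0 lower at unadjusted p under 0.05, 2 and 0 by DESeq2, 2 higher adjusted over the list alone). The immediate early genes were at 0.75 (camera adjusted p = 0.0216, or 0.533 with an estimated correlation), and 0 of 17 passed edgeR (1 higher and 0 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone), and the smooth muscle genes at 0.70 (camera adjusted p = 0.0178, or 0.575 with an estimated correlation), and 0 of 12 passed edgeR (5 higher and 0 lower at unadjusted p under 0.05, 1 and 0 by DESeq2, 1 higher adjusted over the list alone). The host genes of small nucleolar and Cajal body RNAs were at -0.47 (camera adjusted p = 0.0117, or 0.575 with an estimated correlation), and 0 of 28 passed edgeR (1 higher and 6 lower at unadjusted p under 0.05, 1 and 4 by DESeq2, 0 adjusted over the list alone), and the ribosomal proteins at -0.41 (camera adjusted p = 0.0117, or 0.749 with an estimated correlation), and 0 of 46 passed edgeR (0 higher and 0 lower at unadjusted p under 0.05, 0 and 0 by DESeq2, 0 adjusted over the list alone). The telomerase complex was at -0.18 (camera adjusted p = 0.33). Fatty acid oxidation genes lost their call without N-CM1 (0.0563). Immediate early genes lost their call without N-CM2 (0.0521), N-CM3 (0.0577) or N-CM-B2 (0.0631). Smooth muscle genes lost their call without N-CM2 (0.0762) or N-CM-B2 (0.0631). Small RNA host genes lost their call without N-CM2 (0.124) or N-CM-B1 (0.0836). Ribosomal proteins lost their call without N-CM2 (0.878) or N-CM-B1 (0.374).

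In all, edgeR called 413 genes with BCH001 in non-expanded cells, 255 up and 158 down, and 2888 had an unadjusted p under 0.05. Under TPM scaling 234 rose and 2425 fell (8.80% up, against 61.7%), and DESeq2 called 684 up and 644 down (51.5% up). The count was 172 without N-CM1, 253 without N-CM2, 92 without N-CM-B1 (82 up and 10 down) and 48 without N-CM-B2 (43 and 5). N-CM-B came from the other folder, so batch and compound cannot be told apart in this comparison.

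**Figure D3:**
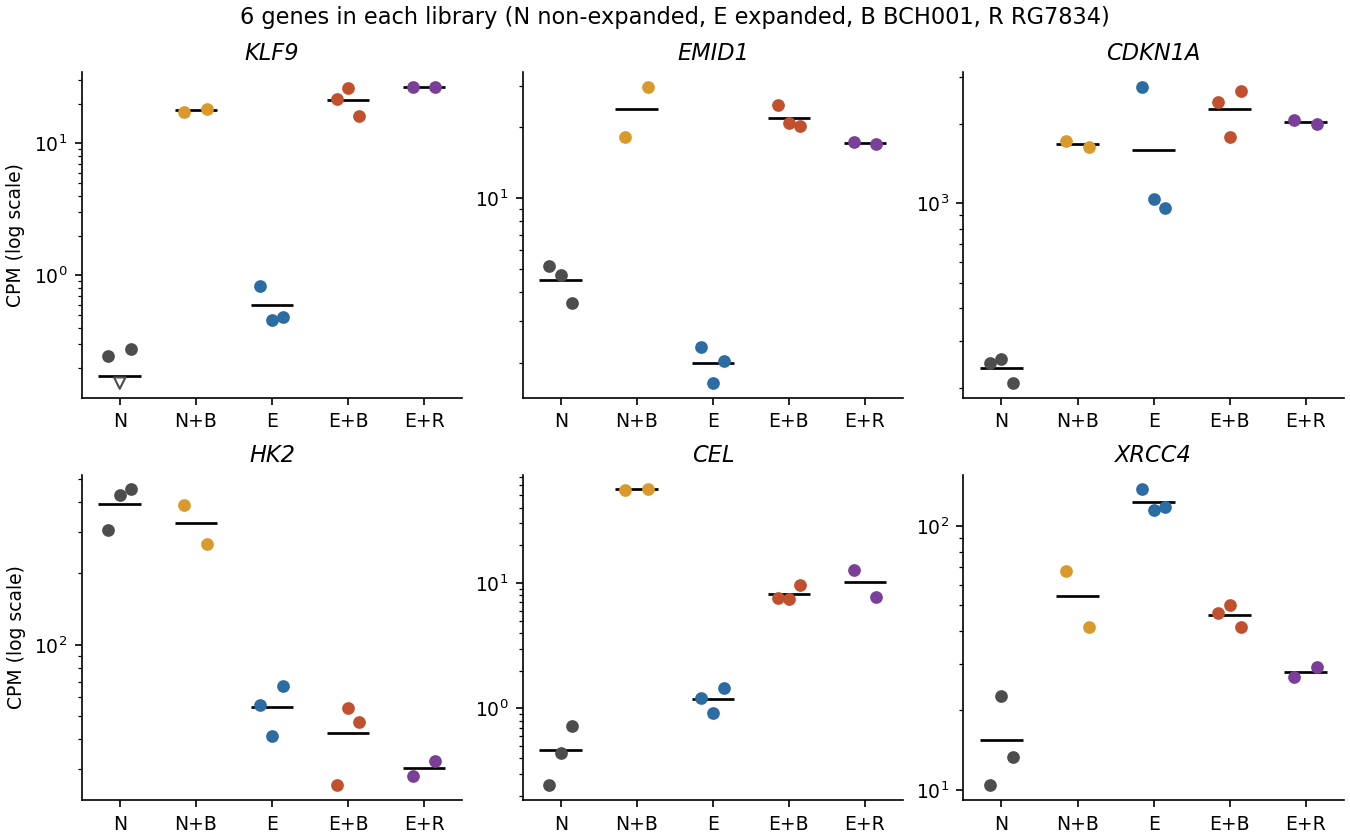
TMM-scaled CPM (y axis, log scale) of KLF9, EMID1, CDKN1A, HK2, CEL and XRCC4 in each library by group (x axis), with a line at the group mean and an open triangle where a library had 0 read pairs (KLF9 in N-CM2). KLF9 lies between 16.04 and 26.6 CPM in the compound-treated libraries and at or below 0.831 in the untreated ones, and HK2 lies at or above 265 CPM in the non-expanded libraries and at or below 66.8 in the expanded ones.

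The BCH001 responses of expanded and non-expanded cells share no library. Between them 59 genes rose in both (1.41 expected of independent lists), 38 fell in both (1.37 expected) and 1 went opposite ways (3.08 expected). The shared leading genes included SLC38A8, KLF9, HR, ADRB1, UNCX and CPXM1. Of the 413 genes called in non-expanded cells, 379 went the same way in expanded cells (91.8%), and of the 280 called in expanded cells, 252 did so in non-expanded cells (90%). The log2 fold changes correlated at 0.33 across genes, against -0.0043 in simulations of unchanged groups, with a covariance of 0.650, and those of RG7834 in expanded cells correlated with those of BCH001 in non-expanded cells at 0.35. Expansion and BCH001 in non-expanded cells shared 83 rises (5.62 expected), CDKN1A and TP53I3 among them, and 42 falls (3.10 expected), with 4 genes opposite (8.48 expected). The fold changes of these 2 comparisons, which share the N-CM libraries, correlated at 0.39 against a simulated 0.41 (0.382 to 0.435), and the covariance was 0.754 against 0.326. Expansion and BCH001 in expanded cells, which share E-CM with opposite sign, correlated at -0.22 against a simulated -0.52, and the covariance was -0.430 against -0.345. Expansion and RG7834 in expanded cells correlated at -0.16 against -0.42, with a covariance of -0.334 against -0.346.

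**Figure D4:**
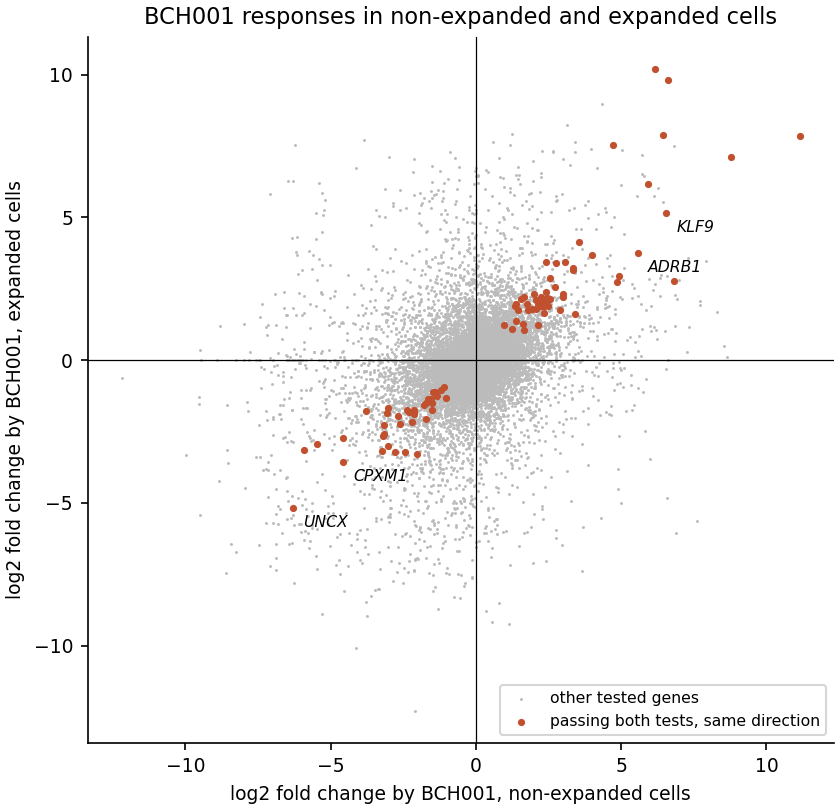
Log2 fold change with BCH001 in non-expanded cells (x axis) and in expanded cells (y axis) for the 19749 tested genes, with the 97 genes that passed both tests in the same direction in orange. KLF9 lies at 6.54 and 5.16, and ADRB1 at 5.56 and 3.75.

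Whether BCH001 acted differently in expanded and non-expanded cells was tested as the difference between its effects. CEL rose less in expanded cells, by a difference of -4.07 ± 0.54 SE (edgeR adjusted p = 0.0401), with group means of 0.470 CPM in N-CM, 55.8 in N-CM-B, 1.19 in E-CM and 8.22 in E-CM-B. XRCC4, a DNA end-joining factor (chromosome 5, 83077498 to 83353787, plus strand), differed by -3.24 ± 0.42 (edgeR adjusted p = 0.0401), with 15.5 CPM in N-CM, 54.3 in N-CM-B, 124 in E-CM and 46.1 in E-CM-B. CDKN1A was at -2.29 ± 0.51 (edgeR adjusted p = 0.204). CEL and XRCC4 were the only genes of 19749 that edgeR's quasi-likelihood test called, where 1329 had an unadjusted p under 0.05, DESeq2 called 163 and the replicate block gave 5. CEL lost its call without N-CM1 (0.0965), N-CM2 (0.103), E-CM1 (0.128), E-CM-B1 (0.1003), E-CM-B2 (0.0854), E-CM-B3 (0.113), N-CM-B1 (0.381) or N-CM-B2 (0.272). XRCC4 lost its call without N-CM1 (0.0965), N-CM3 (0.0594), E-CM1 (0.128), E-CM-B1 (0.1003), E-CM-B2 (0.0854), E-CM-B3 (0.113), N-CM-B1 (0.381) or N-CM-B2 (0.0556). CDKN1A gained a call without E-CM3 (0.0493). The count was 0 without N-CM1, E-CM1, E-CM-B1, E-CM-B2, N-CM-B1 or N-CM-B2, 1 without N-CM2 (XRCC4) or E-CM-B3 (another gene), 16 without E-CM2 and 44 without E-CM3. N-CM-B came from the other folder with no dose or timing stated, so batch, dose and cell state cannot be told apart.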

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

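The explanations below, and the receptor and FOXO lists, were drawn up after the comparisons had been tested. The batch tests, the tests for more mitochondria and for 1 library that stands apart and the splits of the libraries were also chosen after the values they measure were seen, the others before. A test of the difference itself showed that the effect of BCH001 was lower in expanded than in non-expanded cells for 2 genes and 11 lists. The differences were -3.24 for XRCC4 and -4.07 for CEL (log2, edgeR adjusted p = 0.0401 for both). The list medians of the difference, with the camera adjusted p and the one with an estimated correlation, were -0.38 for sarcomere genes (0.0105 and 0.458), -2.82 for cardiac stress markers (7.18e-05 and 0.383), -0.75 for cholesterol synthesis (4.41e-05 and 0.383), -0.96 for G2/M phase (1.62e-09 and 0.458), -1.01 for S phase (6.41e-11 and 0.383), -0.63 for replication-dependent histones (0.00204 and 0.458), -0.94 for p53 targets (1.96e-07 and 0.383), -1.14 for senescence genes (0.00794 and 0.492), -0.87 for YAP targets (0.00354 and 0.383), -1.42 for immediate early genes (4.58e-07 and 0.146) and -1.22 for smooth muscle genes (0.000176 and 0.458), and the histone median was 0.01 under TPM scaling. With the replicate block camera called 3 more, small RNA host genes (0.0202) and epicardial genes (0.0321) higher and endoderm and hepatic genes lower (0.0315). XRCC4 and CEL each lost their call without any 1 of 8 libraries given above. Sarcomere genes lost their call without N-CM2 (0.0775), E-CM2 (0.0849) or E-CM-B3 (0.0792). Replication-dependent histones lost their call without E-CM2 (0.13). Senescence genes lost their call without N-CM3 (0.0749) or E-CM1 (0.149).

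BCH001 changed 97 genes the same way in expanded and in non-expanded cells. After each library's trend with GC content and transcript length was removed, in the fit with the replicate block, 100% of these 97 genes, 94 of them with a GC value, kept their direction and at least 50% of their change in both comparisons (86 passed both tests, against 95 before), which argues against such trends as the whole cause. A batch that follows the folder is argued against as well, since 91.8% of the genes called in non-expanded cells went the same way in expanded cells, where both groups come from 1 folder. Targets of hormone receptors and of FOXO stay open as explanations. Of 16 thyroid hormone receptor targets, 3 rose in non-expanded cells. Their median was 1.07 (camera adjusted p = 0.000603, or 0.0584 with an estimated correlation). In expanded cells it was 0.39 with BCH001 (camera 0.112 or 0.279) and 0.45 with RG7834 (camera 0.124 or 0.283). There 0 rose and KCNA5 fell by 2.26 with BCH001. FOXO targets were at 0.52 in non-expanded cells (camera 0.00943 or 0.134) and 0.19 and -0.05 in expanded cells. Glucocorticoid receptor targets were at -0.069, -0.57 and -0.53 in that order. To exclude a list, its median plus 2 SE had to stay under 0.5 in each comparison. The glucocorticoid receptor missed this in non-expanded cells alone (SE 0.356), and FOXO with BCH001 in both states. KLF9, HR, ADRB1 and ABCD2 were left off the thyroid list because their values had been seen, and an effect of PAPD5 inhibition itself stays open, untested.

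The 7 compound-treated libraries had 14.1% to 20.0% of read pairs on the mitochondrial chromosome and the 6 untreated ones 1.85% to 6.93%. The lowest BCH001-treated expanded library, at 14.1%, lay above the highest untreated one of its folder, at 6.93%, which argues against a batch that follows the folder. The nuclear-encoded respiratory chain changed by at most 0.243 of the mitochondrial change. With BCH001 in expanded cells, RG7834 and BCH001 in non-expanded cells its upper limits were 0.55, 0.64 and 0.86. They lay below 0.97, 1.14 and 1.21, 50% of the mitochondrial change. The limits (2 SE over genes) omit the spread between libraries, so more mitochondria per cell stays open. Loss of cytoplasmic RNA from leaky cells stays open: the nuclear-retained long non-coding RNAs changed by at most 0.251 of the mitochondrial change, but their upper limit of 1.05 with BCH001 in expanded cells lay above 0.97. An action of the compounds on mitochondrial RNA was not tested.

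Expansion and BCH001 in non-expanded cells changed 125 genes the same way, both measured against N-CM. Dividing the 3 N-CM libraries between the comparisons, in 6 ways, left 1 comparison of each division with 1 N-CM library. The labels do not call these libraries separate cultures, so the divisions cannot decide on shared chance values. The shared calls were 38 up and 12 down without N-CM1, 50 and 21 without N-CM2 and 71 and 25 without N-CM3. This argues against 1 N-CM library that stands apart as the whole cause. The correlation of these fold changes across all genes was 0.0401 to 0.214 in the divisions, with fewer controls, against 0.39 undivided. Part of it may come from shared controls. A response common to expansion and BCH001 stays open, untested, and for N-CM-B batch and group cannot be told apart.

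Splits of 6 libraries into 3 and 3, fitted on those libraries alone, number 10, too few for a share under 0.05. For expansion the real split called 98 genes and 14 lists and the highest other 0 and 15, with 1 and 2 splits at or above the real value. For BCH001 in expanded cells the real split called 5 genes and 12 lists and the highest other 0 and 14, with 1 and 4 splits at or above the real value. Among the 4 splits that part all 3 numbered pairs, the highest other called 0 genes in both, and 15 and 11 lists.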

How the results depend on the processing

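The fits on the larger folder and the comparison of E-CM-B with N-CM-B were added after the data were seen. Counts below are in the order expansion, BCH001 in expanded cells, RG7834 in expanded cells, BCH001 in non-expanded cells, BCH001 against RG7834, the difference between the BCH001 effects, and expansion in BCH001-treated cells. The edgeR test called 822, 280, 194, 413, 0, 2 and 432 genes. DESeq2 on the same genes called 2078, 1221, 1058, 1328, 9, 163 and 1398. Without a low-count filter the counts were 1786, 1276, 1139, 1188, 113, 394 and 1359. A fit on the compared groups alone gave 98, 5, 0, 849, 1, 0 and 731, where it had fewer libraries for the dispersion, and of the 98 it called 37.8% up, against 52.9%. With limma on TPM they were 1788, 1062, 1428, 2659, 0, 13 and 606, and against a fold change of 1.5 they were 229, 77, 81, 176, 0, 0 and 107. The larger folder alone gave 214 and 51 for the first pair of comparisons, and 673 and 105 with the block. RLE size factors, the filter at 5 CPM and leaving out mitochondrially encoded genes kept each count within 1.5 times. Except where a stricter test reduces the calls by construction, the cause was not tested.

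The replicate block gave 1668, 536, 841, 1146, 0, 5 and 1260 genes. The difference between the BCH001 effects includes the groups taken as paired. In the remaining 4 same-numbered deviations correlated at 0.0156 to 0.0602 between E-CM and E-CM-R and at -0.0314 to 0.0327 between N-CM and N-CM-B. They were 0.0233 to 0.0341 between E-CM-B and E-CM-R and -0.0373 to 0.0263 between E-CM-B and N-CM-B, over 2 pairs each. In the first pair of comparisons and in that difference the block changed no call of a gene or list named in the text other than those given there.

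Leaving out each library in turn gave 353 to 1048, 81 to 980, 5 to 983, 48 to 326, 0 to 0, 0 to 44 and 14 to 278 genes. Where this leaves a group with 1 library, that library is assumed to vary like the other groups. Of the lists, camera called 16, 13, 9, 18, 3, 11 and 15, and 13 to 18, 9 to 17, 6 to 18, 9 to 18, 1 to 8, 11 to 14 and 12 to 15 without 1 library. With an estimated correlation it called 0 in each comparison, while fry, which tests each list by itself, called 9, 2, 2, 3, 0, 0 and 8 by direction and 22, 13, 14, 21, 1, 6 and 15 without regard to direction. Between the compounds camera called 6 lists in the fit on the compared groups alone and 5 with the block.

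The correlation of fold changes between BCH001 and RG7834 in expanded cells was 0.65, with 0.80 under the filter at 5 CPM, 0.86 over genes called in either comparison, and 0.541 to 0.751 without 1 library. For expansion against BCH001 in expanded cells it was -0.22, with -0.017 under that filter, -0.093 over called genes and -0.408 to -0.138 without 1 library. Expansion against RG7834 went from -0.16 to 0.051 under that filter, the 1 result that reversed, with -0.376 to -0.114 without 1 library. BCH001 in expanded against non-expanded cells was at 0.33, with 0.54 under that filter, 0.65 over called genes and 0.193 to 0.349 without 1 library, and RG7834 against BCH001 in non-expanded cells was at 0.35, with 0.55, 0.70 and 0.210 to 0.358. The cause was not tested.

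Of the summary results, 57 of those under other settings and 82 of those without 1 library stayed within their limits, and 58 and 50 moved. Of the values of called genes under an alternative, 2540 kept the call, 848 lost it and none reversed, and of those of genes not called, 1962 stayed so and 80 became calls. TERC and TERT had too few read pairs to test in these libraries. At 2 to 3 libraries a group most 2-fold changes in the simulated data were missed.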

Other observations

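The comparison of E-CM-B with N-CM-B, expansion in BCH001-treated cells, was chosen after the data were seen. FGF12 rose by 5.70 ± 1.00 (edgeR adjusted p = 0.0173) and the ADP-ribosyltransferase gene ART5 from 25.7 ± 2.84 to 479.6 ± 96.4 CPM (4.22 ± 0.51, edgeR adjusted p = 0.00311). The protease inhibitor A2M was at -5.58 ± 1.03, from 1857 ± 35.4 (SD, n = 2) to 38.8 ± 16.5 CPM (SD, n = 3), and the adaptor gene STAC at -4.51 ± 0.55 (edgeR adjusted p = 0.00311). Of 16 hypoxia response genes, 8 fell and 8 did not pass (14 lower adjusted over the list alone). The hypoxia genes had a median log2 change of -1.77 (camera adjusted p = 1.52e-10, or 0.397 with an estimated correlation), where SLC2A3 was at -2.87 ± 0.31. Of 17 glycolysis genes, 4 fell and 13 did not pass (11 lower adjusted over the list alone). The glycolysis genes had a median log2 change of -0.97 (camera adjusted p = 2.17e-07, or 0.400 with an estimated correlation), where HK2 was at -2.95 ± 0.33. FGF12 lost its call without N-CM-B1 (0.193) or N-CM-B2 (0.158). ART5 lost its call without N-CM-B1 (0.0679) or N-CM-B2 (0.0541). A2M lost its call without E-CM-B1 (0.0963), E-CM-B2 (0.0549), E-CM-B3 (0.0529), N-CM-B1 (0.103) or N-CM-B2 (0.0902).

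Of 34 G2/M genes in this comparison, 3 fell and 31 did not pass (27 lower adjusted over the list alone). The G2/M genes had a median log2 change of -1.47 (camera adjusted p = 6.64e-13, or 0.397 with an estimated correlation). Of 36 S phase genes, 5 fell and 31 did not pass (24 lower adjusted over the list alone). The S phase genes had a median log2 change of -1.33 (camera adjusted p = 3.82e-10, or 0.397 with an estimated correlation). Of 17 immediate early genes, 5 fell and 12 did not pass (7 lower adjusted over the list alone). The immediate early genes had a median log2 change of -1.92 (camera adjusted p = 9.25e-08, or 0.11 with an estimated correlation). The transcription factor E2F1 was at -2.19 ± 0.33 and the nuclear receptor NR4A1 at -2.79 ± 0.42 (edgeR adjusted p = 0.00861 for both). Cholesterol synthesis was at -0.65 (camera adjusted p = 0.000102, or 0.397 with an estimated correlation). In all, edgeR called 432 genes, 95 up and 337 down, and 3277 had an unadjusted p under 0.05, while DESeq2 called 496 up and 902 down (35.5% up, against 22.0%). The count was 61 without E-CM-B1, 278 without E-CM-B2, 146 without E-CM-B3, 16 without N-CM-B1 and 14 without N-CM-B2, with no rise in the last pair. E2F1 lost its call without N-CM-B1 (0.0836) or N-CM-B2 (0.0902). NR4A1 lost its call without N-CM-B1 (0.0784) or N-CM-B2 (0.0761). Of the 822 genes called on expansion of untreated cells, 758 went the same way here (92.2%), with 49 rises (2.09 expected of independent lists) and 104 falls (6.60 expected) called in both and 1 gene opposite (9.28 expected). Folder and group cannot be told apart in this comparison.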
